A study of Mus musculus with 2 samples.

How the data were processed

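Chromatin immunoprecipitation with sequencing (ChIP-seq) was performed on frozen BCA tissue from mouse atherosclerotic lesions with an antibody against KLF4, a zinc finger transcription factor. Per the labels' protocols, nuclei were sonicated, the lysates were cleared, complexes of protein and DNA were recovered with the antibody, and Illumina libraries were made. Animals were C57BL/6 mice kept on a Western diet, and the labels describe the tissue as a mixture of smooth muscle cells (SMC), epithelial cells, macrophages and other cells. There was 1 library labelled WT and 1 library labelled KO. The labels do not say which gene was deleted or in which cells, and the series title names KLF4 and smooth muscle cells.

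Per the submitters' processing notes, Bowtie 1.0, SAMtools 0.1.18 and the mouse genome build mm10 were used. The authors deposited 1 peak list per library, and each list was read here as a separate call on that library. The peak names in the deposited files show that MACS made the lists. The version of MACS, its control library, its settings and any treatment of duplicate or multiply placed reads are not given in the sources used here. The score of each peak in the deposited lists was read as 10 times the negative log10 of the peak's p-value, which is how older MACS versions write it. The lowest scores, 50 in the WT list and 50.03 in the KO list, correspond to a p-value of 1e-05 on that scale. The score depends on a library's depth and background, so scores were used to rank peaks within a list and not to compare levels between lists. The lists hold no read counts, so the depth of both libraries is unknown, and no depth-based floor or interval can be given. A missing peak means only that none was called at the authors' threshold.

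Peak lists were compared with bedtools 2.31.1. A peak was called shared when it overlapped a peak of the other list by at least 1 bp. The overlap expected by chance came from 1000 random placements of the KO peaks on their own chromosomes, between the lowest and highest annotated or called position. Shares of peaks are given with 95% Wilson intervals, which cover counting error over peaks only. Medians of shared and library-specific peaks were compared by two-sided permutation tests with 100000 resamples, for which 1e-05 is the smallest p that can be given. With 1 library per group there was no replicate error, no test of the genotypes was possible, and every test compares these 2 lists. Tests over peaks treat neighbouring peaks as independent, so their p-values are likely too small. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.

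Gene spans, names and types came from the NCBI RefSeq table of assembly GRCm38.p6, which has the chromosome coordinates of mm10. The table holds 21887 protein-coding genes, 10429 pseudogenes and 12727 long noncoding RNA genes on the chromosomes. It gives no strand, exons or transcript starts, and no genome sequence was used here. The design fixed before the data were examined assigned peaks within 10 kb of a transcript start. In its place, a gene was assigned every peak whose midpoint lay in its span or within 10 kb of either end, which had been listed as an alternative and misses no gene whose start is within 10 kb. Places near promoters were likewise replaced by the 1 kb around either end of a gene span. The planned count of KLF motifs, its alternatives, and the removal of peaks in repeats were not run because they need a sequence. The position of peaks was compared with 1000 random placements of the same peaks on the same chromosomes. Peaks on unplaced or unlocalised sequences, 73 in WT and 53 in KO, entered the overlap but no analysis of genes or positions.

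A set of 17 gene lists with 205 distinct genes, all found in the table, was fixed before the data were examined. For each list, the number of members with a peak was set against 10000 random lists of protein-coding genes of the same size and the same distribution over gene-length quintiles. The result is a percentile, counting ties by 50%, and describes these libraries. Named peaks are the 10 highest-scoring WT-only peaks with a protein-coding gene within 10 kb, the 5 highest such shared peaks, the 5 highest such KO-only peaks, the Klf4 locus, and up to 4 members of each list with the highest scores. Other list members with a peak are named to complete the counts. The procedure was checked on simulated lists for the comparison of WT with KO. All 300 planted shared peaks were recovered, 421 peaks were found in pseudogenes after 400 had been planted, and a list with 5 planted members among 21887 genes reached percentile 99.995, while 0 of the other 16 lists lay in the upper 2.5%. Apart from the planted peaks, the simulated peaks were placed at random on the chromosomes. The check therefore does not cover the list percentiles when peaks favour genes. Alternatives covered the overlap rule, a stricter score limit, equal list sizes, the gene window, the Y chromosome and unplaced sequences, and pseudogenes.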

Results

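KLF4 occupancy was profiled in atherosclerotic lesions of mice on a Western diet, with 1 WT library and 1 KO library. The comparison asks which sites called with the KLF4 antibody in WT lesions were not called in KO lesions. The WT list held 2251 peaks and the KO list 1153. Median peak width was 156 bp in WT and 140 bp in KO, and the peaks covered 468.2 kb and 219.5 kb. Since each genotype had a single library, the differences below are between these 2 lists and have no replicate check.

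Most peaks were called in 1 library only. Of the WT peaks, 356 overlapped a KO peak, which is 15.8% (95% Wilson interval 14.4 to 17.4%), and 1895 were WT-only. Of the KO peaks, 370 overlapped a WT peak, which is 32.1% (29.5 to 34.8%), and 783 were KO-only. On the chromosomes, 311 WT peaks overlapped a KO peak, against 0 to 4 when the KO peaks were placed at random. When the WT list was reduced to its 1153 top-scoring peaks, 283 WT peaks overlapped a KO peak and 870 did not. Most WT peaks thus also lacked a KO partner at equal list size. The cut left the KO list as it was, so it does not test whether peaks were missed in KO at a lower depth.

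Shared peaks scored higher than library-specific peaks in both lists. In WT, the median score was 180.0 for shared peaks and 82.6 for WT-only peaks, a difference of 97.4 (permutation test over peaks, two-sided, p = 1e-05, the smallest possible). In KO, the medians were 112.7 for shared and 55.5 for KO-only peaks, a difference of 57.2 (permutation p = 1e-05). Within the KO list, 78.0% of KO-only peaks scored below 60, close to the list's lowest score of 50.03, compared with 9.19% of shared peaks. Within the WT list, these shares were 19.9% of WT-only and 6.46% of shared peaks. In the highest decile of WT scores, 55.6% of peaks (49.0 to 61.9%) had a KO partner, and in the highest decile of KO scores 99.1% (95.3 to 99.8%) had a WT partner.

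**Figure D1:**
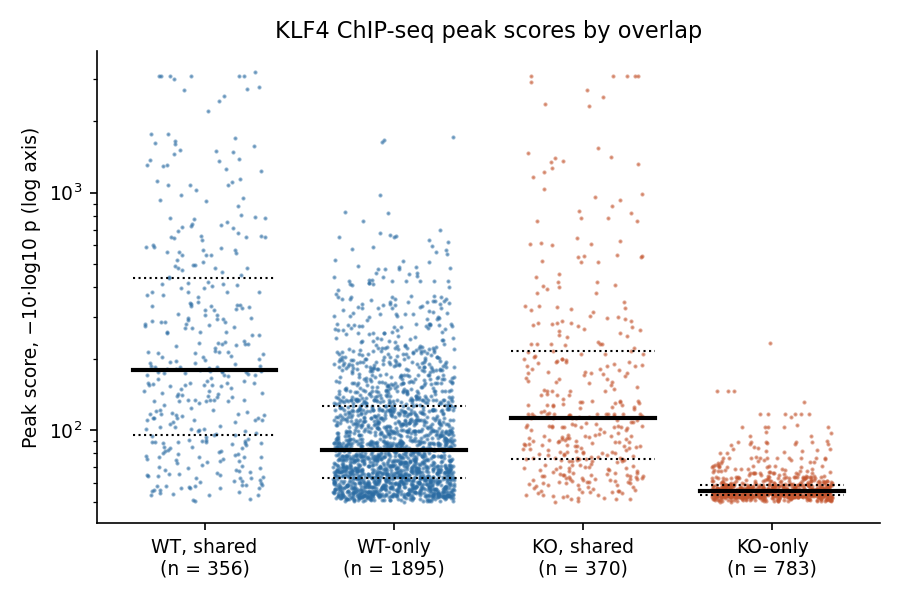
Score of each peak on a log axis, read as 10 times the negative log10 of the peak p-value, for WT peaks (blue) and KO peaks (orange) that were shared or called in 1 library only. Thick lines are medians and dotted lines are quartiles; within each list the shared peaks score higher, with medians of 180.0 against 82.6 in WT and 112.7 against 55.5 in KO, and levels are not comparable between lists.

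The highest-scoring WT-only peaks lay in Fn1, Tmsb4x and Sparc. The top 10 WT-only peaks near protein-coding genes fell in the spans of 8 genes and scored 654.1 to 1720. Fn1 (gene 14268), which encodes the matrix glycoprotein fibronectin, held 3 of them, on chromosome 1 at 71603612 to 71603968 (score 1720), 71613762 to 71614059 (1629) and 71597532 to 71597826 (675.4). The peak in Tmsb4x (gene 19241), which encodes the actin-binding protein thymosin beta 4, lay on chromosome X at 167207258 to 167207538 and scored 1667. Sparc, a collagen-binding matrix protein gene, had a peak on chromosome 11 at 55401894 to 55402175 with a score of 975.1. Col1a1, a type I collagen chain gene, had a peak on chromosome 11 at 94951134 to 94951290 with a score of 763.6. Ybx1, which encodes a nucleic acid binding protein, had a peak on chromosome 4 at 119278926 to 119279167 that scored 699.9. Pabpc1, which encodes the cytoplasmic poly(A) binding protein, had a peak on chromosome 15 at 36608313 to 36608541 that scored 655.8. Eif5a, a translation factor gene, had a peak on chromosome 11 at 69919154 to 69919339 with a score of 654.1. The remaining peak, on chromosome 4 at 43663853 to 43664403 with a score of 820.0, lay in the span of Fam221b, and its midpoint fell in the pseudogene Gm12481.

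Several of these genes held many narrow WT peaks and no KO peak. Col1a1 held 11 WT peaks across its span of 16.8 kb (chromosome 11, 94936224 to 94953042), with a median width of 158 bp. Eif4g2, a translation regulator gene, held 10, Fn1 and the non-muscle myosin gene Myh9 held 9 each, and Pabpc1 held 8. In WT, 829 protein-coding spans held a peak and 117 held 3 or more. In KO, 357 held a peak and 9 held 3 or more, with at most 5 in a gene, in Sfi1, a gene that held 9 WT peaks.

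**Figure D2:**
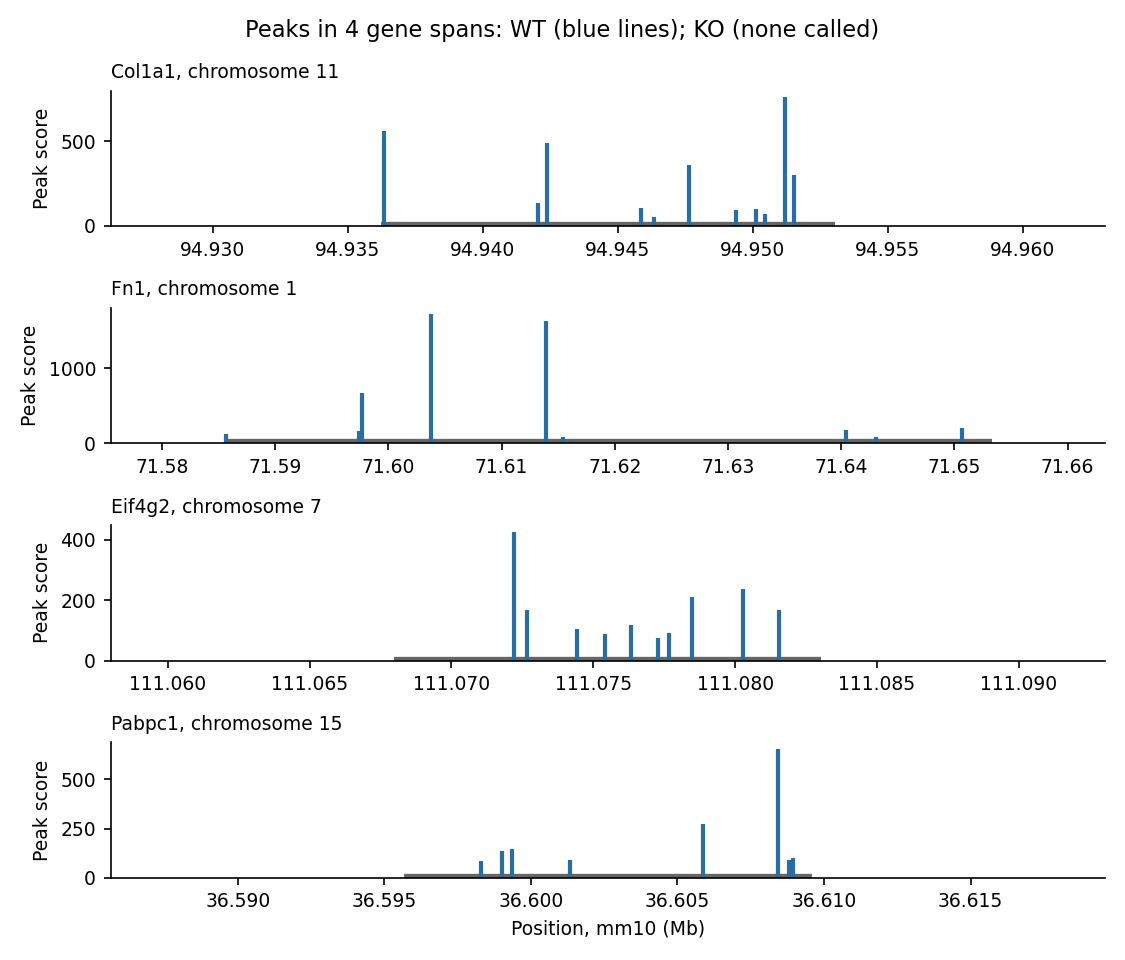
Peak score against position (mm10, Mb) in 4 gene spans (grey bars) with 10 kb on either side; each blue line is a WT peak at its midpoint. Col1a1 shows 11, Fn1 9, Eif4g2 10 and Pabpc1 8 WT peaks spread over the span, and 0 KO peaks were called in any of these windows.

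WT-only peaks favoured genes and pseudogenes, and KO-only peaks did not. Of the 1867 WT-only peaks on chromosomes, 63.3% (61.0 to 65.4%) had their midpoint in a protein-coding span, against 37.0% for random placements (highest 40.5%), a 1.71-fold excess. In pseudogene spans, which are disabled copies of genes, the share was 21.0% (19.3 to 23.0%) against 1.12% at random (highest 1.93%), an 18.7-fold excess. Within 1 kb of either end of a protein-coding span lay 14.5% (13.0 to 16.2%) of WT-only peaks, against 2.95% at random, a 4.93-fold excess. Of 776 KO-only peaks on chromosomes, 38.9% (35.5 to 42.4%) lay in protein-coding spans and 1.80% (1.08 to 3.01%) in pseudogene spans, both within the range of random placements. Within 1 kb of a gene end, the KO-only share was 3.22% (2.19 to 4.71%), against 2.84% at random. Shared WT peaks lay in protein-coding spans less often than random placements did, at 26.7% (22.1 to 31.9%) against a median of 36.3% and a lowest value of 28.6%. At or above the median score this share was 30.1% (lowest random value 26.5%), and without the Y chromosome 29.9% (29.5%), both inside the random range. Shared KO peaks stayed below it in both settings, at 26.2% (lowest 29.2%) and 28.9% (31.3%). In pseudogene spans lay 3.86% (2.22 to 6.62%) of shared WT peaks, just above the highest random value of 3.54%, and 4.01% (2.36 to 6.74%) of shared KO peaks (highest 3.70%). These were only 12 WT and 13 KO peaks. Without the Y chromosome the WT share was 3.96%, equal to the highest random value, and the KO share 4.12% (3.78%). At or above the median score they were 4.02% (3.61%) and 4.32% (3.32%). The placements moved each peak separately, although some peaks lay side by side, so the random ranges are likely too narrow.

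**Figure D3:**
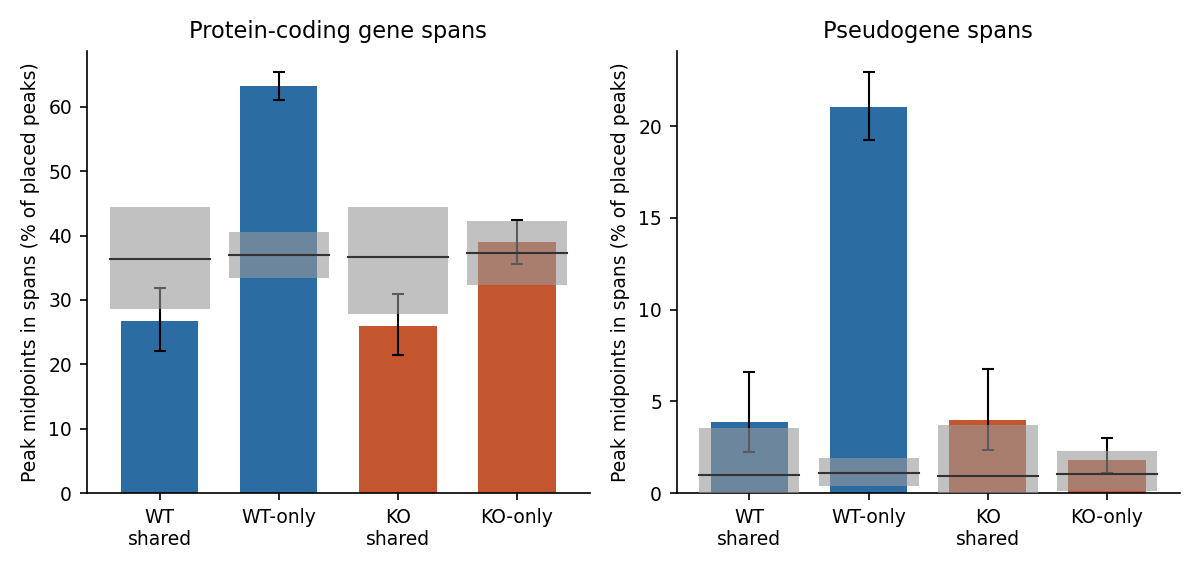
Percent of peaks on chromosomes whose midpoint lay in protein-coding spans (left) or pseudogene spans (right), with 95% Wilson intervals; grey bands are the range and dark lines the median of 1000 random placements. WT-only peaks stand far above the bands, at 63.3% and 21.0%, while KO-only peaks lie within them.

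The highest shared peaks were not in the genes named above. The 5 highest near protein-coding genes lay in the spans of Chl1 (chromosome 6, 103648995 to 103649343, WT score 2799), Aida (chromosome 1, 183299132 to 183299590, score 2721), Myo3a (chromosome 2, 22589150 to 22590286, score 2205) and Lars2 (chromosome 9, 123461799 to 123462249, score 1774), and 2.94 kb from Tmem125 (chromosome 4, 118546978 to 118548741, score 2728). Chl1 encodes a neural adhesion molecule, Myo3a an unconventional myosin and Lars2 the mitochondrial leucyl-tRNA synthetase. The gene names give positions only and do not show that KLF4 bound there. All 5 WT peaks in Myo3a were shared and lay between 22587504 and 22590286, in a span of 390.8 kb. Of the shared WT peaks, 12.6% (9.58 to 16.5%) lay on unplaced sequences, against 1.48% (1.02 to 2.13%) of WT-only peaks (Fisher's exact test over peaks, two-sided, p = 1.46e-19). That p-value takes neighbouring peaks as independent. The Y chromosome held similar shares, 9.27% and 8.44% (Fisher's exact test, p = 0.606).

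The 5 highest KO-only peaks near genes scored 103.4 to 116.7, close to the median of shared KO peaks, 112.7. They lay in Immp2l (chromosome 12, 41777934 to 41777993), Stxbp4 (chromosome 11, 90538814 to 90538871) and Gm5724 (chromosome 6, 141747549 to 141747606), each with a score of 116.7 and a width of 58 to 60 bp. Arih1 (chromosome 9, 59424418 to 59424549, score 104.9), a ubiquitin ligase gene, and Rex2 (chromosome 4, 147030576 to 147030958, score 103.4) followed. Tied scores limit the ranking of KO-only peaks. Of the 783 KO-only peaks, 423 (54.0%) had a score held by 5 or more peaks, compared with 283 of 1895 WT-only peaks (14.9%). The cause of the ties was not tested.

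Within 10 kb of a span, 1362 protein-coding genes had a WT peak and 513 had a KO peak. Of these, 156 had both, 1206 WT alone and 357 KO alone. Independent lists of these sizes would share 31.9 genes. That value takes no account of gene length, although long genes gather more peaks in both lists. Genes near a shared peak also count in both, so the excess partly restates the peak overlap. Klf4 itself (chromosome 4, 55527137 to 55532475) had no peak within 100 kb in either library. The nearest WT peak lay 2625 kb away and the nearest KO peak 2055 kb away, so its locus gives no check of the genotype labels.

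Genes of the extracellular matrix and of smooth muscle contraction carried WT peaks more often than length-matched random lists. Of 20 matrix genes, 9 had a WT peak, against a random mean of 1.32, and 0 of the 10000 random lists had as many. These were Fn1, Col1a1, Col1a2 (score 368.4), Col3a1 (330.9), Thbs1 (311.5), Mmp2 (238.2), Col5a1 (194.1), Vcan (189.3) and Tnc (113.2), which encode fibronectin, collagen chains, thrombospondin 1, a gelatinase, versican and tenascin C. In KO, 1 of the 20 had a peak, in Col5a1, with a score of 52.0 (percentile 74.3). Of 16 contractile genes, 5 had a WT peak against a random mean of 1.09 (percentile 99.8): Tpm2 (272.9), Vcl (139.1), Myl9 (117.1), Tagln (67.5) and Acta2 (59.6), the genes of a tropomyosin, vinculin, a myosin light chain, transgelin and smooth muscle actin. The Tagln peak also lay in the span of Pcsk7. With WT cut to its top 1153 peaks, 3 of the 5 remained, and Tagln and Acta2 scored below the median of the WT list, 88.3. In KO, 2 different members had a peak, Myocd (52.3), the coactivator myocardin, and Synpo2 (51.2), for a percentile of 94.3. Myh11, Cnn1 and Smtn had none in either list. Leaving out peaks in pseudogene spans, a setting chosen after the data were seen, kept 9 matrix genes and 5 contractile genes with a WT peak. The random lists were matched on length alone, and the excess was not particular to these lists. In families chosen after the data were seen, 15 of 21 genes of heterogeneous nuclear ribonucleoproteins (random mean 1.29), 16 of 81 ribosomal protein genes (3.94) and 14 of 56 genes of translation initiation factors and related symbols (3.51) had a WT peak.

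Among lists of other cell types, fibroblast markers alone lay in the upper 2.5% of random lists in WT, and this call depended on the gene window. Of its 10 genes, 3 had a WT peak (percentile 98.7), Col1a1, Fbln1 (99.3) and Pi16 (145.1), but the Pi16 peak lay 7.33 kb from the gene, in the span of Mtch1. The percentile was 95.9 with the span plus 2500 bp, 94.9 within 10 kb of the span's ends and 94.6 for the nearest gene, while it was 99.8 both with peaks at or above the median score and with WT cut to 1153 peaks, and 99.1 without pseudogene peaks. No list lay in the upper 2.5% in KO, except that growth factor signalling reached percentile 99.0 (Pdgfd and Hbegf) when only peaks at or above each list's median score were kept. Macrophage markers had WT peaks at 2 of 13 genes (percentile 87.9) and KO peaks at 0. The peak counted for Itgam lay 8.53 kb from it in the pseudogene Gm45700, and that counted for Cd68 lay in Eif4a1, so neither lay in a macrophage gene. Mesenchymal stem cell markers had 2 of 8 in WT, Itgb1 (354.8) and Cd44 (202.5), at percentile 94.7, which rose to 98.3 with peaks at or above the median score or with WT cut to 1153 peaks. Within 10 kb of the span's ends, only Itgb1 remained (percentile 78.9). Epithelial markers had 1 in each library, Krt14 in WT (68.3) and Krt19 in KO (56.3). Endothelial and osteochondrogenic lists had 0 within 10 kb in both libraries, though the nearest-gene rule within 100 kb gave KO peaks to Tek, Cldn5 and Bmp2. T cell markers had 0 in WT and 1 in KO, Cd2 (56.8).

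Pluripotency factors, the KLF family, inflammatory cytokines and adhesion genes, and TGF-beta and BMP signalling had 0 members with a peak within 10 kb in either library, with random means of 0.63, 1.07, 0.98 and 1.12 in WT. Lists of this size near so few peaks cannot show a depletion, and with the nearest gene within 100 kb the KLF family had 1 member in each library, Klf17, and TGF-beta and BMP signalling had 1 in KO, Bmp2. Phagocytosis and lipid handling genes had 3 WT members (percentile 94.9), Cd36 (146.0, with the peak 8.89 kb away), Lrp1 (79.4) and Apoe (68.5), and 2 KO members, Olr1 (61.0) and Msr1 (51.1). Growth factor signalling had Fgfr1 (77.7) and Vegfa (54.9) in WT, and Hbegf (61.1) and Pdgfd (59.6) in KO. Cell cycle regulators had Ccnd1 (189.8) and Trp53 (100.4) in WT. The peak counted for Trp53 lay 6.46 kb away, in the pseudogene Rps27-ps2 within Wrap53. Of the transcription factors of the smooth muscle phenotype, Srf, the serum response factor gene, had a WT peak (66.2). Across all lists, 29 of 205 genes had a WT peak and 9 a KO peak, with 1 in common, Col5a1. The WT peak lay in the gene's own span for 24 of the 29, and 15 held 2 or more, while the 9 KO genes held at most 1 each, with scores of 51.1 to 61.1.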

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

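Peaks on unplaced or unlocalised sequences, 73 in WT and 53 in KO, are flagged because they lay outside every comparison of genes; 45 of the WT peaks were shared. No control library was at hand, so these counts alone show nothing about their origin. Of the tests in this part, those of the share on pseudogenes, of gene ends, of depth at matched scores and of unplaced sequences were chosen after the result was seen.

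The first pattern is that WT-only peaks lay in protein-coding spans and on pseudogenes. At matched scores, the peaks in spans had a KO partner less often than those outside. This does not decide on a KO library of lower depth. The peaks outside may include repeated sequence that gathers reads in any library. Equal WT scores would not make both kinds of peak equally easy to call in KO. Of 598 WT peaks outside protein-coding and pseudogene spans, 581 were paired with a WT peak inside them of a score within 5% (median scores 78.3 for both). A KO partner was found for 6.37% (4.66 to 8.65%) of the peaks inside and 34.3% (30.5 to 38.2%) of those outside (exact sign test over pairs, p = 6.14e-40). Several peaks of a gene can enter as separate pairs, so the p-value treats neighbouring peaks as independent. Among the 249 pairs whose outside peak scored at or above the WT median, the shares were 14.1% inside and 59.0% outside. The pairing replaced an earlier comparison above a score limit, which pointed the same way but left the scores unmatched. A lower depth in KO, alone or with another cause, stays open. Reads copied from spliced RNA (complementary DNA in the WT library) may account for the pseudogene part: of 63 pseudogenes named after a parent gene and holding a WT-only peak, 63.5% had a parent with a WT peak, against a median of 17.5% and at most 34.9% for random picks. Reads of an enriched parent placed also on its copy stay open as well. The interval of that share, 51.1 to 74.3%, is not below 50%. Several of these pseudogenes share a parent, such as Rps19 and Rps18 with a WT peak and Rpl19 without. The share counts such parents repeatedly, and its interval is too narrow. KLF4 binding stays open too, since the 21.0% of WT-only peaks in pseudogenes is the pattern itself and decides nothing without a sequence. For the protein-coding part, binding and RNA-derived reads cannot be told apart here. The 14.5% of WT-only peaks near a gene end decides neither without strand, exons or sequence. Single genes with many narrow WT peaks, such as Col1a1 with 11, and the gene families with an excess or a deficit of WT peaks also bear on this. These were not tested against either explanation, since expression was not measured here. Loss of KLF4 binding in KO stays an open biological explanation.

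The second pattern is that shared peaks scored highest. Repeated or misassembled sequence that gathers reads in any library is a candidate explanation, since 12.6% of shared WT peaks lay on unplaced sequences, against 1.48% of WT-only peaks. This test first pooled the Y chromosome with unplaced sequences (21.9% against 9.92%) and was narrowed once the parts had been seen; the Y chromosome alone, with 9.27% against 8.44% (Fisher's exact test, p = 0.606), gives it no support. KLF4 binding kept in the KO tissue, for instance in cells without a deletion, cannot be told apart from repeated sequence. The labels do not say which gene was deleted or in which cells. Of the shared WT peaks, 26.7% lay in protein-coding spans, which does not decide without a motif search, and no control library was used here.

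The third pattern is that KO-only peaks scored close to the threshold. Reads gathered by chance without regard to genes may account for them, since 38.9% lay in protein-coding spans, within the central 95% of random placements (33.9 to 40.6%). No biological explanation was tested for this pattern.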

How the results depend on the processing

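With 1 library per group no replicate could be left out. No paired analysis was possible because there is 1 library of each genotype. Of 64 recomputed main results, 46 stayed within 1.5 times the reported count, or within the interval or on the same side of the test, and 18 moved. The overlap rules, the score limit and the cut of the WT list for overlaps were planned; that cut for genes, the gene windows, and the settings without the Y chromosome, unplaced sequences or pseudogenes were chosen after seeing the data. Keeping only peaks at or above each list's median score left 872 WT-only and 298 KO-only peaks, 676 genes with WT peaks alone, 113 with KO alone and 90 with both, and 3 list genes with a KO peak, by construction since fewer peaks remain. For positions, shared status was kept from the full lists, which left 855 WT-only and 234 KO-only peaks on chromosomes at that limit. The WT-only share moved to 67.0% in protein-coding spans and to 27.5% in pseudogene spans. The KO-only shares moved to 33.3% and 0.43%, from above to below the random median. They went from 1.04 to 0.99 times the median and from 1.75 to 0.5 times it, and stayed within the random range. The cause was not tested. Cutting WT to 1153 peaks left 870 WT-only peaks and 661 genes with WT alone, again with fewer peaks. Without the Y chromosome, 69.2% of WT-only peaks lay in protein-coding spans, since the number in spans stayed at 1181 while the total fell to 1707. Within 2500 bp of a gene end lay 28.5% of WT-only and 7.47% of KO-only peaks, by construction of the wider window. Counting only peaks within 10 kb of either end of a span, which leaves out the middle of long genes, left 188 genes with KO alone, 85 with both, and 4 list genes with a KO peak. The difference in median WT score was 98.2 with reciprocal overlap of 50% and 62.5 with edges within 1 kb (permutation p = 1e-05 for both). Without peaks in pseudogenes, 1502 WT-only peaks and 1063 genes with WT peaks alone remained, and macrophage markers and cell cycle regulators each fell from 2 to 1. The number of lists in the upper 2.5% of random lists was 3 in WT and 0 in KO, and ranged from 2 to 4 in WT and from 0 to 1 in KO over the alternatives. Of 60 recomputed counts for the 10 lists with a WT member, 17 moved by over 1.5 times, all lower. Over all 17 lists, the only increases came with the nearest gene within 100 kb, in 1 list in WT (the KLF family, 0 to 1) and in 4 in KO. The unknown depth limits every statement on missing peaks, and the planned motif and repeat alternatives were not run.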

Other observations

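Gene families outside the fixed lists, chosen after the data were seen, differed in how often they held WT peaks. Of 21 genes of heterogeneous nuclear ribonucleoproteins, which package and process RNA, 15 had a WT peak within 10 kb, against a random mean of 1.29, and 0 of 10000 length-matched lists had as many. They included Hnrnpa2b1 and Hnrnpk, and 1 of the 21 had a KO peak. Of 81 ribosomal protein genes, 16 had a WT peak (random mean 3.94) and 2 a KO peak (0.80). Of 56 genes of translation initiation factors and related symbols, 14 had a WT peak (3.51) and 2 a KO peak (1.15). Receptor families of sensory neurons went the other way: 7 of 1110 olfactory receptor genes (random mean 49.7) and 4 of 355 vomeronasal receptor genes (18.2) had a WT peak, and no random list of either size had fewer. In KO, the counts were 10 (random mean 11.0) and 8 (4.39). Keratin genes lay near chance in WT, at 4 of 53 (random mean 3.24), and had 2 in KO (0.54).

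WT-only peaks lay in 309 pseudogenes with a median span of 1204 bp, compared with 14 pseudogenes for KO-only peaks. Examples were Ybx1-ps2 (chromosome 6, 37686681 to 37686994, score 661.7), Rps19-ps6 (chromosome 12, 110898066 to 110898227, 509.8), Actg-ps1 (chromosome 8, 46229209 to 46229298, 444.4) and Gapdh-ps14 (chromosome 8, 41609149 to 41609240, 412.1). Ybx1 and Rps19, the parents of the first pair, held WT peaks as well, and Gapdh did not. Chromosome 11 held 8.31% of WT peaks and 3.99% of KO peaks, and chromosome X 4.35% and 1.99%.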
